A study of Homo sapiens with 2 samples.

How the data were processed

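ATAC-seq libraries of the human oral squamous carcinoma line CAL27 were compared, 1 from untreated cells and 1 from cells given 10 mM lactate for 24 h, with group membership taken from the treatment labels. Nuclei were incubated with Tn5 transposase, per the labels' protocols. The submitters' processing notes name fastp 0.20.0, BWA 0.7.12, MACS2 2.1.0 and the genome build hg38. The file headers name MACS 2.2.7.1 instead. Per the file headers, the authors called peaks separately in each library, without a control library, from alignment files whose names point to uniquely mapped, deduplicated tags. The settings were a q-value threshold of 0.05, no fragment model, a shift of 100 bp upstream, an extension of 200 bp, all remaining duplicates kept, summit calling on, and a genome size of 3099750718 bp. The shift and extension centre each 200 bp tag on its 5' end, which is where Tn5 cut. Tags were counted as single ends, and whether both ends of a read pair entered was not checked.

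The deposited lists give, for each summit, a pileup, a signal that per the file headers is the number of extended tags covering the summit, without scaling for depth. They also give a fold enrichment, the ratio of the pileup to the local background that the authors' peak caller computed with 1 added to each. The start, end, width and summit position were deposited in base pairs. Neither p-values nor q-values were among the columns used here. The local background was therefore recovered from the deposited pileup and fold, and the −log10 of the Poisson p was recomputed from both. No row fell below the background of 1.177 tags for the untreated or 0.994 for the lactate library that the tag total, the extension and the genome size imply. Fold enrichment and recomputed −log10 p are each peak's own values and served only to rank or filter peaks within a list.

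The untreated file header counts 18248413 tags of 129 bp and the lactate header 15401276 tags of 130 bp. The untreated list holds 124208 summits in 98404 regions and the lactate list 145262 summits in 122654 regions. A region with several summits was counted once, with its highest pileup and fold. Chromosomes 1 to 22 and X were used. Regions on Y, 92 and 96, and on unplaced contigs, 160 and 159, were left out of the comparisons for the untreated and lactate lists.

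Regions were called shared when they overlapped a region of the other list by at least 1 bp, and library-only otherwise. Counts from the interval code equalled those of bedtools 2.31.1. Gene coordinates came from a RefSeq table of the GRCh38.p14 assembly, the same build as hg38, for 19970 protein-coding genes on the chromosomes used. That table carries no strand, so promoters could not be told from the other end of a gene. The planned promoter window became a gene-end window of 1 kb on each side of either annotated end, and exons were not told from introns. Of 394 list entries, 1 (LOR, an alias of more than 1 gene) was left out. No genome sequence was used here, so the 24 planned motif searches were not run.

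With 1 library per group there is no estimate of variation between cultures, no test and no p-value. Intervals are exact 95% binomial intervals for shares and exact conditional Poisson intervals for ratios of tag counts. They cover counting error only, and tags amplified by PCR or taken at a summit chosen for its height are not independent draws. For each of 21 gene lists fixed in advance, the lactate-only minus untreated-only regions within 50 kb of a member's end were divided by all regions there. The percentile of that share among 10000 random lists of equal size, matched on the tenth of the number of regions within 50 kb, describes these libraries alone. Random genes were drawn singly, so the clustering of list members along a chromosome was not matched. The lists cover glycolysis, lactate transport, proposed lactylation enzymes, hypoxia, squamous identity and differentiation, mesenchymal transition, invasion, angiogenesis, cytokines, interferon, cell cycle, growth factors, immediate early genes, oxidative stress, autophagy and housekeeping, plus markers of fibroblasts, leukocytes, endothelium and neurons.

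Named genes followed a rule fixed in advance. It takes the 10 genes with the strongest gene-end region in each library alone and, per list, up to 4 members with a gene-end region in 1 library alone. It adds LDHA, LDHB, SLC16A1, SLC16A3, HCAR1, EP300, TP63, KRT5, KRT14, VEGFA, HK2 and MYC, and the 5 strongest library-only regions away from gene ends. Strength was fold enrichment, the planned fallback where neither q nor p is listed.

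The comparison of summit heights was added after the data had been seen. Overlapping regions of both lists were merged, the highest pileup of each library was divided by its total tags, and the lactate value was divided by the untreated one. A relative ratio divides this by the median ratio of shared regions in the same of 20 bins of summit tags of both libraries together. Single-summit regions of 218 to 226 bp, called narrow regions, were left out of it. Also added after seeing the data were lists without the narrow regions, ranking by recomputed −log10 p, naming only regions that the other list does not overlap anywhere, counting list members whose ratio interval leaves 1, and bins of 1 library's summit tags in the comparison with gene density. The scripts were run several times, and regions overlapped just outside a gene-end window were noticed after the first run. Alternatives chosen in advance were −log10 p of at least 7, equal numbers of the strongest regions, 50% overlap, a 500 bp gap, gene-end windows of 500 bp and 2.5 kb, a 10 kb neighbourhood, and all contigs.

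Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The simulation of the common-factor prediction was run after its result had been seen. On simulated data, the overlap code recovered 3000 of 3000 regions, 95.5% of 2000 ratio intervals held the true ratio, and 94.5% of 400 unchanged gene lists fell inside the middle 95% of percentiles. The simulated lists held no neighbouring genes with regions in common.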

Results

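Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts open DNA and attaches sequencing adapters, in CAL27, a cell line established from a squamous carcinoma of the tongue. The series asks how added lactate changes the chromatin of these cells. It holds 1 library of untreated cells and 1 of cells kept in 10 mM lactate for 24 h, with 18248413 and 15401276 tags. With 1 library per group no difference has a replicate check, and the values compare these libraries rather than the conditions. All intervals are 95% intervals that cover counting error only. Lactylation profiles and RNA-seq of the same design were not analysed here.

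More regions were listed as accessible in the lactate library, and most accessible regions of the untreated library were among them. On chromosomes 1 to 22 and X the lactate list held 122399 regions covering 50.21 Mb and the untreated list 98152 regions covering 42.64 Mb, 1.25 times as many regions from fewer tags. Of the untreated regions, 88387 (90.1%, exact binomial interval 89.9 to 90.2) were overlapped by a lactate region, leaving 9765 untreated-only regions. Of the lactate regions, 88461 (72.3%, 72.0 to 72.5) were overlapped by an untreated region, leaving 33938 lactate-only regions. When each list was reduced to its 98152 strongest regions by fold enrichment over local background, the numbers became 18898 lactate-only and 18198 untreated-only regions. At equal length such numbers can differ only where 1 region overlaps several of the other list. Their near equality therefore does not test the excess.

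Regions of 1 list alone were mostly weak ones. The median pileup, the number of extended tags over the summit, was 11 in lactate-only regions against 30 in shared regions of the lactate list. In the untreated list it was 11 against 22. In the strongest 10% of each list by fold enrichment, 99.8% of lactate regions and 99.9% of untreated regions were overlapped by the other list. Of these strongest regions, 67.8% in the lactate and 86.1% in the untreated list belong to the class of narrow regions described further on. In the weakest 10% the shares were 35.7% (34.8 to 36.5) and 71.0% (70.1 to 71.9).

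**Figure D1:**
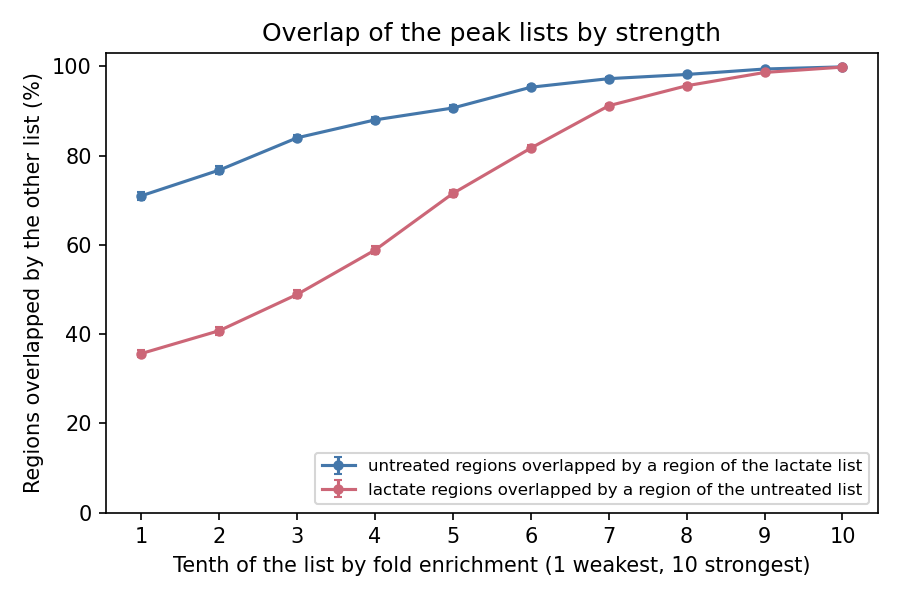
Percent of regions overlapped by the other list (vertical axis) in 10 equal groups of each list by fold enrichment (horizontal axis, weakest to strongest); points are shares and bars exact 95% binomial intervals. The lactate list goes from 35.7% in its weakest group to 99.8% in its strongest, and the untreated list from 71.0% to 99.9%.

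Shared regions were taller in the lactate library almost throughout. At 86803 merged regions present in both lists, covering 46.3 Mb, the mean summit pileup was 34.5 tags in the untreated and 50.9 in the lactate library. These summit tags made up 16.4% and 28.7% of the total tags of the untreated and lactate libraries. Without the narrow regions described further on, the median ratio of lactate to untreated summit tags, each divided by its library's total tags, was 1.66 over 73366 merged regions. It was 1.80 at gene ends and 1.63 elsewhere, and 89.5% of the regions had a ratio above 1. Split into 4 equal groups by the summit tags of both libraries together, the regions had median ratios of 1.29 in the group with the fewest tags and 1.91 in the group with the most. A shared region had to be called in both libraries, which can hold the ratio nearer 1 where tags are few, by an amount not tested. Single regions are therefore set below against regions with equal summit tags, as a relative ratio.

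Regions of 1 list alone were less often at gene ends than shared ones. A gene end here means the sequence within 1 kb of either annotated end of a protein-coding gene. Of the lactate-only regions, 7.27% (7 to 7.55) lay at a gene end, 43.5% elsewhere in a gene and 49.2% outside protein-coding genes. The untreated-only regions divided into 8.12% (7.59 to 8.68), 43.1% and 48.8%, and the shared regions of the lactate list into 14.6% (14.4 to 14.8), 40.2% and 45.2%. Without narrow regions the gene-end shares were 7.56% for lactate-only, 8.34% for untreated-only and 17.5% for shared regions of the lactate list. Library-only and shared regions were not matched on strength here, and the library-only ones were mostly weak. The order of the library-only shares at gene ends turned with the threshold, since at a recomputed −log10 p of at least 7 in both lists they were 8.91% for lactate-only and 6.06% for untreated-only regions.

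Of 19970 protein-coding genes, 12340 (61.8%) had a region at a gene end in both libraries, 1216 in the lactate library alone, 167 in the untreated library alone and 6247 (31.3%) in neither. At equal numbers of the strongest regions by fold enrichment the order turned, with 695 genes in the lactate library alone and 801 in the untreated library alone. It did not turn at equal numbers ranked by recomputed −log10 p, with 741 and 482 genes. Among the 10 genes with the strongest lactate-only gene end, 4 had a region that no untreated region overlapped. They were FKBP1A, the prolyl isomerase that binds FK506 (chromosome 20, 1392601 to 1393374, hg38, pileup 59, fold enrichment 14.6), and FOXO4, a forkhead transcription factor (chromosome X, 71095653 to 71095952, pileup 30, fold 13.1). The others were TBC1D9B (chromosome 5, 179907740 to 179908149, pileup 44, fold 12.6) and ANKRD6 (chromosome 6, 89432901 to 89433306, pileup 28, fold 12.6). At the other 6 genes, SPMIP3, STX11, ADGRV1, MMP25, POLR1H and ENKD1, the region reached into the 1 kb window only in the lactate list, while an untreated region overlapped it outside the window. Among all 1216 genes this applied to 59.

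The 10 strongest untreated-only gene ends were TOGARAM2, CELF2, UMODL1, OR7G3, ZBTB46, OCIAD1, ZNF302, LURAP1L, PRR20G and MFAP5. At 7 of them a lactate region overlapped the listed region outside the window. The other 3 were CELF2, an RNA-binding splicing factor (chromosome 10, 10463371 to 10463589, pileup 22, fold 10.6), whose region is one of the narrow regions described further on, OCIAD1 (chromosome 4, 48861664 to 48861894, pileup 16, fold 7.81) and MFAP5, a microfibril component (chromosome 12, 8645326 to 8645525, pileup 15, fold 7.35). Among all 167 genes, 32 had an overlapping lactate region just outside the window.

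Naming only regions that the other list does not overlap anywhere, and leaving out narrow ones, was done after the values had been seen. In the lactate list it added ALOX12, the 12-lipoxygenase (fold 12.4), CD80, a ligand of T cell costimulation (fold 12.4), SPINK13 (fold 12), LZTFL1 (fold 11.8), CCNE1, the cyclin E1 gene (fold 11.7), and RCSD1 (fold 11.7), with pileups of 23 to 44. In the untreated list it added COL6A5, NXPH2, PENK, SCN2A, SYCP2L, CA8, PRTFDC1 and TAF11L5. Their folds were 5.97 to 6.89 and their pileups 12 to 15. PENK encodes the opioid precursor proenkephalin and SCN2A a neuronal sodium channel.

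Of the 17 genes of lactate transport and sensing, 12 had a gene-end region in both libraries, 4 in neither (SLC16A8, SLC5A8, SLC5A12 and EMB) and LDHC in the lactate library alone. LDHA, the lactate dehydrogenase subunit that favours lactate formation, had 62 untreated and 56 lactate summit tags at its lower-coordinate end (chromosome 11, 18394078 to 18394845). Its ratio was 1.07 (conditional Poisson interval 0.732 to 1.56), which is 0.567 (0.388 to 0.828) relative to regions of equal summit tags. LDHB had a relative ratio of 1.07 (0.631 to 1.83). The lactate transporters SLC16A1 and SLC16A3 had 0.833 (0.566 to 1.23) and 1.03 (0.767 to 1.39). The lactate receptor gene HCAR1 had 0.958 (0.490 to 1.91) at its lower-coordinate end, which need not be the promoter. EP300, an acetyltransferase proposed to lactylate histones, had 0.938 (0.601 to 1.48).

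Among the other genes fixed in advance, VEGFA, the angiogenic growth factor, had a relative ratio of 0.693 (0.455 to 1.06) and the hexokinase gene HK2 0.808 (0.497 to 1.32). The basal keratin gene KRT5 had 0.835 (0.593 to 1.18) and MYC 1.25 (0.917 to 1.73), from 61 untreated and 129 lactate tags. The MYC region lay at the upper-coordinate end of the gene (chromosome 8, 127742255 to 127743586). As strand was not used, it need not be the promoter. Neither library had a region at the outer ends of TP63, the squamous lineage regulator (chromosome 3, 189596746 to 189897276), but 17 untreated and 22 lactate regions lay within the gene. KRT14 had none at its ends or within the gene in either list, with 9 untreated and 11 lactate regions within 50 kb.

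**Figure D2:**
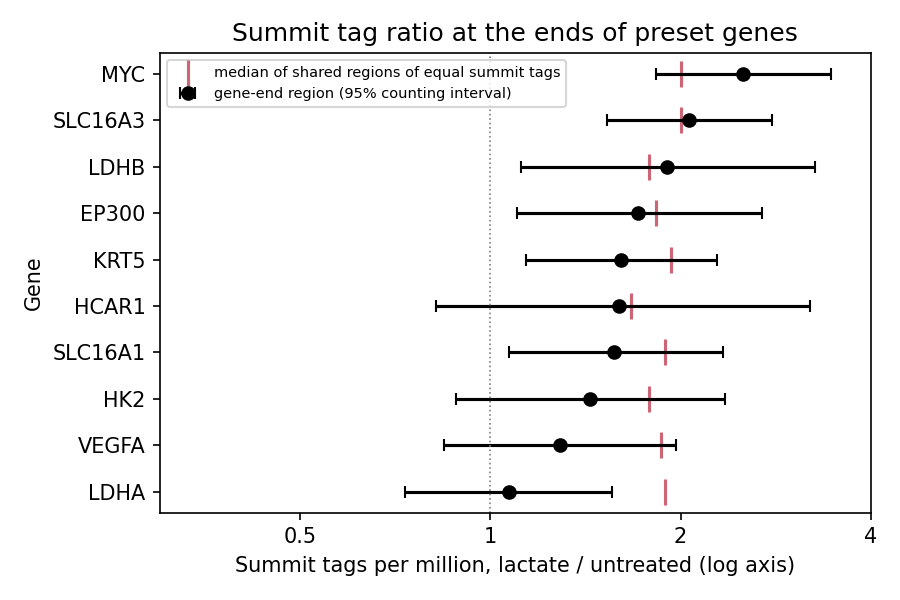
Ratio of lactate to untreated summit tags, each divided by total tags (horizontal log axis) at the tallest shared gene-end region of 10 genes fixed in advance (vertical axis); points are ratios, bars exact 95% counting intervals and vertical marks the median of shared regions with equal summit tags. LDHA, at 1.07, lies below its mark of 1.89, while the intervals of the other genes include theirs.

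Among the fixed gene lists, the interferon response stood lowest in its balance of library-only regions. Within 50 kb of its 21 genes there were 39 lactate-only and 19 untreated-only regions among 230, a net share of 8.70%, at percentile 0.5 of matched random lists, whose median was 17.4%. Of the 21 lists it was the one outside the middle 95%, where chance gives 1.05. Members lying close together, such as IFIT2 and IFIT3 or OAS1 and OAS3, can count the same regions more than once. Random lists were drawn gene by gene and seldom hold such neighbours, so this percentile may be too extreme. At a −log10 p of at least 7 in both lists the percentile of the interferon response was 33.4. At its gene ends 19 members had regions in both libraries and 2 in neither.

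Glycolysis enzymes had a net share of 13.7% (percentile 13.5), with 16 of 20 genes open in both libraries, PFKFB4 (fold 5) and PFKP (fold 3.94) in the lactate library alone and 2 in neither. Lactate transport and sensing stood at 14.8% (percentile 25.8), with a fold of 5.40 at LDHC. The proposed lactylation writers and erasers stood at 18.1% (percentile 58.1). There, 16 of 17 were in both, and the acetyltransferase gene KAT2B (chromosome 3, 20039916 to 20040312, pileup 16, fold 5.86) was in the lactate library alone. The hypoxia response stood at 19.3% (percentile 67.9), with CA12 (fold 3.57) and ANGPTL4 (fold 2.47) in the lactate library alone.

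Squamous keratinocyte identity stood at 16.7% (percentile 43.0), with 19 of 23 genes in both libraries and the keratin gene KRT6B (fold 8.10) and KLF5 (fold 3.53) in the lactate library alone. Keratinocyte differentiation stood at 20.5% (percentile 82.7). Involucrin (IVL, fold 6.28, pileup 44) and S100A8 (fold 4.51) had a gene-end region in the lactate library alone and SPRR3 (fold 5.20) in the untreated library alone. Epithelial-mesenchymal transition stood at 20.8% (percentile 85.3), with TGFB1 (fold 4.59) and the membrane metalloproteinase gene MMP14 (fold 2.89) in the lactate library alone. MMP14 was also the single such member of invasion and matrix remodelling, at 17.4% (percentile 52.5). Angiogenesis stood at 17% (percentile 46.5), with PGF (fold 5.73), ANGPT1 (fold 5.52), NRP2 (fold 3.94) and ANGPTL4 in the lactate library alone.

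Cytokines and NF-kappaB targets stood at 22.2% (percentile 92.0), with NFKB1 (fold 4.83) and LIF (fold 3.28) in the lactate library alone. Cell cycle genes stood at 16.4% (percentile 37.1), with CCNE1 (chromosome 19, 29811363 to 29812128, pileup 44, fold 11.7) and CCND2 (fold 4.32) in the lactate library alone. Growth factor signalling stood at 13.9% (percentile 13) with FGFR3 (fold 8.78), whose region an untreated region overlapped outside the window. AP-1 and immediate early genes stood at 12.7% (percentile 8.5) with EGR3 (fold 6.54), oxidative stress at 22.2% (percentile 89.4) with TXNRD1 (fold 4.08), and autophagy at 13.4% (percentile 13.9) with ULK1 (fold 2.95).

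Housekeeping genes were open in both libraries in 16 of 16 cases, with a net share of 16.7% (percentile 42.5). Among markers of other cell types, 6 of 13 fibroblast, 8 of 16 leukocyte, 8 of 11 endothelial and 7 of 14 neuronal markers had a gene-end region in neither library, against 31.3% of all protein-coding genes. Their net shares were 9.35% (percentile 3.4), 17.9% (53.9), 16.9% (49.5) and 9.02% (3.4). The fibroblast marker PDGFRA (fold 4.26) and the neuronal markers SNAP25 (fold 5.28) and NEFL (fold 4.59) had gene-end regions in the untreated library alone, with pileups of 9 to 14. A lactate region overlapped that of PDGFRA outside the window. SLC17A7 (fold 4.55) had one in the lactate library alone.

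**Figure D3:**
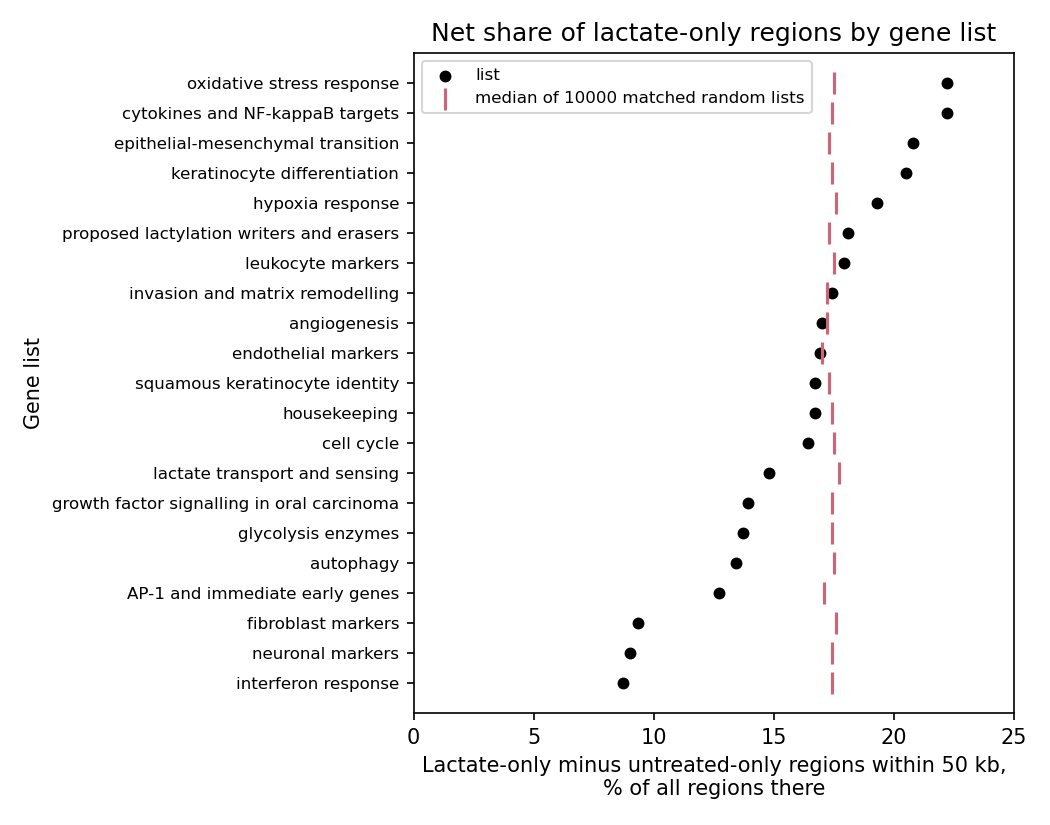
Lactate-only minus untreated-only regions within 50 kb of gene ends as a percent of all regions there (horizontal axis) for 21 gene lists (vertical axis); points are lists and vertical marks the medians of 10000 matched random lists. The interferon response is lowest at 8.70%, and cytokines and oxidative stress are highest at 22.2%.

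The strongest lactate-only region away from gene ends lay within WNK3 (chromosome X, 54239442 to 54239661, pileup 51, fold 21.7), followed by one within OPCML (chromosome 11, 132439494 to 132439727, pileup 42, fold 21.6). The next lay 130452 bp from FAM170A (chromosome 5, 119766274 to 119766492, fold 20.8), 12517 bp from NXPH1 (chromosome 7, 8765478 to 8765698, fold 20) and within MMRN1 (chromosome 4, 89907853 to 89908071, fold 18.6). The strongest untreated-only region lay 7667 bp from ZNF24 (chromosome 18, 35324333 to 35324560, pileup 50, fold 22.6). Others lay 578758 bp from RGS18 (chromosome 1, 191579483 to 191579704, fold 18.4), within XKR4 (chromosome 8, 55183249 to 55183448, fold 16.9), 19046 bp from MYOM3 (chromosome 1, 24036772 to 24036995, fold 13.8) and 738968 bp from LOC105372073 (chromosome 18, 38513656 to 38513855, fold 13.8).

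Of these distal regions, 4 of the 5 in the lactate list and 2 of the 5 in the untreated list were narrow, and narrow regions formed a class of their own in both lists. The width of 219 bp was the commonest above the tag extension of 200 bp, with 6077 untreated and 7074 lactate regions against 213 and 259 at the width just below. The class, taken as single-summit regions from 1 bp below this width to a few bp above it, numbered 17010 (17.3%) in the untreated and 19679 (16.1%) in the lactate list. They made up 94.6% and 95.3% of the 1000 regions with the highest fold enrichment in each list. Of these narrow regions, 94.8% in the untreated and 85.1% in the lactate list were overlapped by the other list. At gene ends lay 2.49% (2.26 to 2.73) and 2.33% (2.13 to 2.55) of them.

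**Figure D4:**
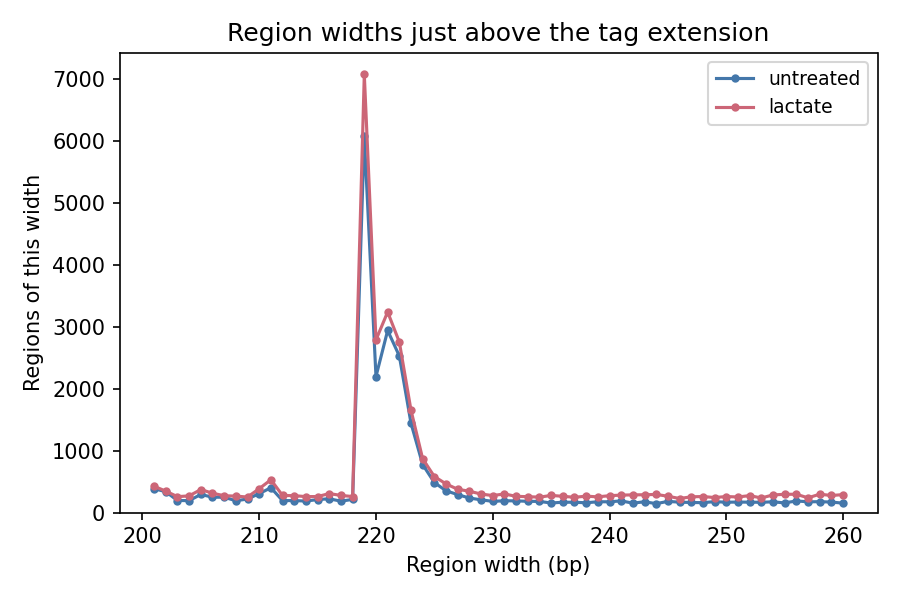
Number of regions (vertical axis) of each width in bp (horizontal axis) above the 200 bp tag extension in the untreated and lactate lists. Both lists have a sharp peak at 219 bp, with 6077 untreated and 7074 lactate regions.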

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

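Alternatives that ranked by recomputed −log10 p or left out the narrow regions were chosen after seeing the data, and the others were set before the data were examined. No paired analysis was possible because each group holds 1 library. Of the alternative values, 32 stayed close to the reported ones and 51 moved beyond the counting interval of a share or 1.5 times a count. The lactate list was the longer one wherever the lists were not made equal in length, and lactate-only outnumbered untreated-only regions in those settings. Lists of equal length gave 18898 lactate-only and 18198 untreated-only regions by fold enrichment, and 17461 and 17040 by recomputed −log10 p. This near equality follows from the construction. At equal length the numbers can differ only where 1 region overlaps several of the other list. Gene ends in 1 library alone numbered 695 for lactate and 801 for untreated by fold, the reverse of the reported order, and 741 and 482 by −log10 p. With −log10 p of at least 7 asked only of the region in question, the library-only regions numbered 18342 and 3887 and the genes 779 and 71.

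Percent overlapped is given for untreated and then lactate regions. It was 90.9 and 71.5 with both lists at −log10 p of at least 7, 81.5 and 80.8 at equal length by fold, 82.6 and 82.2 at equal length by −log10 p, and 86.1 and 68.1 with 50% overlap. It was 92.4 and 74.4 when a region within 500 bp counted, 95.02 and 81.6 with the stricter limit on the region in question, and 85.1 and 67.3 without narrow regions. In the strongest 10% of each list, 50% overlap gave 99.7 and 99.6, and ranking by recomputed −log10 p gave 99.96 and 99.99. Ranking by fold, planned as an alternative, was the reported one.

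Percent at gene ends is given for lactate-only and then untreated-only regions. It was 8.91 and 6.06 with both lists at −log10 p of at least 7, 5.498 and 11.6 at equal length by fold, 8.996 and 10.6 with 50% overlap, 6.07 and 3.84 with the 500 bp gap, and 7.81 and 6.15 with the stricter limit on the region in question. It was 5.13 and 4.49 in windows of 500 bp and 11.99 and 13.02 in windows of 2.5 kb. It was 7.36 and 6.95 without narrow regions, and 7.70 and 7.98 at equal length by −log10 p. Which library had the larger share thus changed with the setting, and the cause was not tested.

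Of the 21 gene lists, 0 lay outside the middle 95% of random lists with a 10 kb neighbourhood, 0 with both lists at −log10 p of at least 7, 3 at equal length by fold, 2 at equal length by −log10 p and 2 without narrow regions. The interferon response had percentiles of 2.6, 33.4, 0.6, 0.5 and 0.4 in that order. The other lists outside were AP-1 and immediate early genes (0.0) and housekeeping (0.3) at equal length by fold, endothelial markers (0.8) at equal length by −log10 p and neuronal markers (0.7) without narrow regions. The motif searches and their alternatives were not run.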

Other observations

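The comparison of summit heights and the choice of genes in this part were made after the data had been seen, as were the tests on the narrow regions, on the tag totals and with bins of 1 library's summit tags. The tests with a common factor and within bins of the summit tags of both libraries together were set before their results were seen, although the window medians used in the latter had been looked at.

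Relative ratios of well-known genes lay on either side of 1. Of 293 list members with a shared gene-end region, 20 had a relative ratio of lactate to untreated summit tags whose interval lay above 1 and 10 one that lay below 1. Counting error alone gives 7.3 on each side. Among all 4255 gene-end regions with at least 100 summit tags, 417 lay above and 386 below, where counting error alone gives 106 on each side. The list members had no minimum of tags, and fewer tags give wider intervals, so the shares of the 2 sets cannot be compared. Since intervals beyond 1 occurred widely among gene-end regions, such an interval alone does not set a gene apart. These intervals leave out variation between libraries. In the hypoxia list EGLN1, an oxygen-sensing prolyl hydroxylase gene, stood at 2.19 (1.26 to 4.02), the mitophagy receptor gene BNIP3 at 2.13 (1.26 to 3.77) and DDIT4 at 1.33 (1.01 to 1.76), and 12 of 17 members lay above 1. Among immediate early genes EGR2 (1.64, 1.07 to 2.57), DUSP1 (1.46, 1.02 to 2.12), IER3 (1.44, 1.08 to 1.93) and FOSL2 (1.40, 1.01 to 1.96) lay above 1, while over the list 9 of 19 members stood higher and 9 lower than 1. The growth factor list had ERBB2 (1.77, 1.06 to 3.08), ERBB3 (1.41, 1.07 to 1.86) and HES1 (1.40, 1.04 to 1.89) above 1, with 12 of 23 members higher and 10 lower. The ERBB3 region (chromosome 12, 56103954 to 56105065) lay beyond the gene's upper-coordinate end at 56103505. As strand was not used, the gene-end regions named in this part need not be promoters of the genes they are listed under. None of the lists tested lay outside the middle 95% of random lists by its median ratio, the hypoxia list being at percentile 93.5 and the cytokine list at 5.5.

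Members of 1 pathway also had relative ratios on both sides of 1. Division by a median places shared regions on both sides by construction, so a value below 1 need not mean fewer lactate tags. Before that division the ratios were 1.2 at IL6, 1.21 at NFKBIA, 1.07 at LDHA and 1.33 at ENO1. They were 1.03 at CDKN2A and 1.17 at GRHL2, while IFIT3 stood at 0.806. Relative ratios follow. In the cytokine list IL6 (0.623, 0.436 to 0.891) and the NF-kappaB inhibitor gene NFKBIA (0.650, 0.435 to 0.972) lay below 1 and the adhesion molecule gene ICAM1 (1.57, 1.04 to 2.41) above. In the interferon list IFIT3 (0.482, 0.244 to 0.928) lay below and IRF1 (1.74, 1.25 to 2.47) above. Among glycolysis enzymes LDHA (0.567) and ENO1 (0.688, 0.497 to 0.955) lay below, and PGK1 (1.61, 1.06 to 2.5) and GPI (1.41, 1.01 to 1.99) above. Among cell cycle genes E2F1 (1.79, 1.24 to 2.64) lay above and CDKN2A (0.569, 0.349 to 0.926) below. KRT6A (2.24, 1.18 to 4.54) lay above and the epithelial regulator gene GRHL2 (0.618, 0.428 to 0.892) below.

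Of the gene-end regions with at least 100 summit tags, the highest relative ratios were at the end shared by ARV1 and TTC13 (chromosome 1, 230978662 to 230979362), with 30 untreated and 149 lactate tags and a relative ratio of 2.94 (1.98 to 4.51), SCAI with 48 and 209 tags (2.58, 1.88 to 3.61) and ABHD11 with 34 and 146 tags (2.54, 1.74 to 3.81). The lowest were at MIOS, a regulator of mTORC1 signalling, with 94 and 71 tags (0.448, 0.324 to 0.616), the end shared by ACOT1 and RIOX1 with 78 and 58 tags (0.456, 0.319 to 0.649) and PRR16 with 75 and 56 tags (0.458, 0.318 to 0.656).

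Lactate-only regions with a −log10 p of at least 7, narrow ones left out, numbered 16071, against 3190 untreated-only ones. KCNAB2, a potassium channel subunit gene, had 10 of them within 50 kb of its ends among 20 lactate regions, and APC2 had 9 among 19. Near APC2 on chromosome 19, ADAMTSL5 and REEP6 had 8 each. In the untreated list KLHL2 had 4 untreated-only regions among 14, TANC2 4 among 16 and RAI1 4 among 19. Neighbouring genes can count the same regions.

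Of shared regions with at least 100 summit tags, those with the lowest ratios before adjustment lay away from gene ends. The lowest was on chromosome 1 (143212957 to 143213449) with 102 untreated and 33 lactate tags, a ratio of 0.383 (0.251 to 0.573), and several lay close together on chromosome 16, such as 46389634 to 46390942 with 381 and 168 tags (0.522, 0.433 to 0.628). No regions were masked here for repeats or mapping problems, and whether these regions are of that kind was not tested.

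The first pattern is the excess of lactate-only over untreated-only regions. Fewer tags cannot have produced it, because the untreated library had 1.18 times the tags of the lactate library, but lower enrichment of the untreated library may account for part of it. With the summit tags of every lactate region scaled by 1 common factor of 0.617, 23959 regions were predicted to miss the untreated threshold. That is 77.3% of the 31001 lactate-only regions, narrow ones left out. It lies between the limits of 80% and 50% set in advance for calling lower enrichment the cause or not. The factor came from 13807 strong regions and applies to tags not divided by library totals. Shared regions with fewer tags had lower ratios of lactate to untreated tags, so the 77.3% depends on this choice. In simulated lists with a true common factor the same calculation gave 114% to 120%. For untreated-only regions it gave 30.2% to 38.2%, against 1.82% of the 8886 found. The simulated sites had an even background and Poisson noise alone, while the deposited lists have a local background. The simulated percentages are therefore no benchmark for the 77.3% or the 1.82%. Lower enrichment and an effect of lactate cannot be told apart with 1 library per group.

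The second pattern is the class of narrow regions, which hold the highest folds in both lists. Chance stacks of tags are argued against by the 94.8% of untreated narrow regions that recur in the lactate list. Unenriched background is argued against by their median log2 ratio of 0.64, near the 0.73 of other shared regions. A candidate explanation is tags whose ends are fixed by local sequence, since the commonest width exceeds the extension by 19 bp and 2.49% of the untreated ones lie at gene ends, against 9.96% (8.85 to 11.2) of slightly wider regions. Chromosomes 4, 13 and X hold 16.9% of the untreated narrow regions and 8.95% of the others. The sequences were not examined here, and a biological explanation was not tested.

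The third pattern is a higher ratio of lactate to untreated summit tags in gene-dense parts of the genome. Over 563 windows of 5 Mb the median log2 ratio had a rank correlation with the number of genes of 0.584 across windows, which are not independent replicates, and the median ratio was 1.53 in the sparsest and 1.73 in the densest of 4 groups of windows. Taller regions in gene-dense windows were weighed as a source by taking off the median of regions with equal summit tags of both libraries together, which left a correlation of 0.151. That adjustment also removes a true gain in lactate tags, because the gain itself moves a region to a higher bin, and with bins of untreated tags alone the correlation was 0.526 and with bins of lactate tags alone −0.0963. Region height and an effect of lactate on gene-dense chromatin therefore cannot be told apart with these libraries, and GC content was not tested.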
